A study of Mus musculus with 4 samples.

How the data were processed

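RNA sequencing was analysed from bone-marrow Lin-Kit+ cells of mice, the fraction that lacks the surface markers of mature blood lineages, carries the Kit receptor and holds hematopoietic stem and progenitor cells. Per the labels' protocols, 2000000 cells went into each library, total RNA was extracted with Trizol and libraries followed the standard Illumina procedure. The 4 libraries comprised 2 from wild-type (WT) mice and 2 from mice without Asxl1 (KO), and the labels supplied the genotype and the replicate number. No label says that the replicates were separate animals. Xist and Y-linked transcripts differed between the 2 libraries of each genotype, so these were not 1 animal measured again, and p-values measure a spread between libraries that holds differences between animals, sex among them.

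Reads were aligned with STAR 2.3.1t and the genome build was mm9, per the submitters' processing notes. The read counter, the gene annotation, the handling of strand and of reads that match several places, and the scaling tool are not given in the sources used here. The deposited table holds 1 signal value per locus and library: read counts that the authors multiplied by 1 factor per library, as the values themselves show. Within each library 100% of the values were whole multiples of the smallest value above 0, within 0.001 of a read. One read was worth 1.30 in WT replicate 1, 1.22 in WT replicate 2, 0.758 in KO replicate 1 and 0.825 in KO replicate 2. Dividing by these steps recovered 46597871, 49764454, 83586916 and 76688583 reads, in the same order, so the KO libraries were deeper. A count of 0 allows up to 3 reads, or 3.89, 3.66, 2.27 and 2.48 on the deposited scale. Such floors and all counting intervals cover counting error only.

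The table has 22849 rows. Of these, 17956 describe single loci, 3122 of which merge several gene names with a plus sign, and their reads cannot be divided between the merged genes. Another 4893 rows join a pair of neighbouring loci with a comma and hold 0.0619% to 0.0676% of the reads of a library. The joined rows were left out of the comparisons and examined separately. Coordinates are those of the deposited table. Reference annotation of a later build served only to match older gene names. No column of the table was left unused.

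A count test had been chosen before the data were examined, on the assumption that the table held raw counts. Because the deposited unit was a scaled signal, the test was limma 3.58.1 with a mean-variance trend on log2(value + 1), with genotype as the only term, in R 4.3.3. Fold changes are therefore on the log2(value + 1) scale, which understates the change of loci with few reads. Single loci with a value of at least 10 in at least 2 libraries were tested, 13764 in all. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The planned count test, the edgeR 4.0.16 quasi-likelihood test with TMM scaling, was run on the recovered reads as an added alternative and called 2839 loci.

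Lists of genes, 35 in number, were fixed before the data were examined. For each, members past the threshold were counted over all loci and adjusted over the list alone. The lists were compared with all other tested loci by camera with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. With 2 residual degrees of freedom that correlation is estimated from little data, so a list lost with it is not shown to be unchanged. Which correlation is right could not be checked here. Loci within 10 Mb of Asxl1 were compared with all others by a two-sided Fisher's exact test.

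Genes were named by a rule fixed in advance. It took Asxl1, the 12 higher and the 12 lower loci with the largest log2 fold change among called loci with separated libraries and a CPM of at least 1 in a group, and the 3 most abundant called loci. Predicted and clone names, antigen receptor segments and pseudogenes were left out of that part. From each list it took up to 4 called members with the largest change, or the 2 with the smallest p where no member was called. Genes outside the rule are identified where they appear. Some loci that the rule or the joined rows gave are not reported here.

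The fit was tested on simulated data for the KO and WT comparison, with reads drawn for the 13764 loci and 50 loci changed at each fold size. It called 50% of loci changed 1.5-fold, 58% of those changed 2-fold, 76% of those changed 3-fold and 98% of those changed 4-fold, all with the right sign, and 7.47% of its calls were false. On the same simulated reads the edgeR test called 60% of loci changed 1.5-fold, and 12.0% of its calls were false. A list shifted 1.5-fold was called by camera, as was 1 of the 34 other lists. The simulation drew loci independently of each other, so it cannot test the preset correlation. It also changed far fewer loci than were called in the data, so its shares need not carry over. Replicates of a genotype differed by more than sampling noise, with a chi-square per degree of freedom of 19.5 in WT and 48.1 in KO, so no library was counted as a duplicate.

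Alternatives listed before the data were examined were edgeR with RLE or upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a CPM filter, a replicate block, removal of mitochondrial, ribosomal protein, haemoglobin and histone genes, other thresholds and windows, other list tests, and each library left out in turn. Alternatives chosen after seeing the data were edgeR with TMM, with and without the block, pseudocounts of 0.5 and 8, rescaling by TMM, keeping the joined rows, thinning the reads of all libraries to the shallowest, and leaving out the X and Y chromosomes. Figures were drawn with matplotlib. Chromatin data that the series design refers to were not analysed here.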

Results

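Transcripts were measured as normalised read counts per locus in Lin-Kit+ bone-marrow cells from C57BL/6 mice, with 2 WT and 2 KO libraries. The libraries held 46597871 and 49764454 recovered reads in WT and 83586916 and 76688583 in KO. ASXL1 is a chromatin regulator that is often mutated in human myeloid malignancy, and the series relates expression changes to its binding and to that of cohesin, the ring complex that holds sister chromatids together. The comparison of KO with WT addressed which transcripts differ in progenitors that lack the protein. Values are means of normalised read counts ± SD over n = 2 libraries, fold changes are log2 values ± SE of KO over WT, and adjusted p-values are from limma unless another test is named. Replicate 1 of each genotype carried high Xist and replicate 2 high Y-linked transcripts. Values within each replicate pair are therefore also given for Asxl1 and for the interferon and mature neutrophil lists.

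Asxl1 (chromosome 2, 153171874 to 153229743, mm9) matched the genotype labels in every library. Its normalised read count was 9607 ± 191 in WT and 140 ± 8.33 in KO, which is 1.46% of the WT mean. The log2 fold change was -6.09 ± 0.09 (adjusted p = 8.89e-06), with -6.05 in the first replicate pair and -6.13 in the second.

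Loss of Asxl1 was accompanied by lower interferon-stimulated, stem-cell, Hox and lymphoid transcripts and by higher mature neutrophil, immediate-early, inflammatory and erythroid transcripts. These list calls came from camera with a preset correlation and were lost with an estimated correlation (adjusted p = 0.597 to 0.681), the lymphoid and erythroid calls were lost with fry as well, and no B lineage gene was called without WT replicate 1 or without WT replicate 2. Stefin A genes on chromosome 16, which encode inhibitors of cysteine proteases, were among the 12 named loci that rose most, and thrombospondin-1 (Thbs1) rose from 4285 ± 1356 to 36644 ± 8855 (log2 3.11 ± 0.24). Among loci taken by the naming rule, which leaves out clone and predicted names, the G-protein regulator Rgs8 and the interferon-induced Oas1g, Iigp1, Ifi44 and Ifit1 fell most after Asxl1 itself. The most abundant transcripts that changed were the neutrophil genes Ngp, Ltf and S100a9, which rose by 0.93 ± 0.11, 0.89 ± 0.08 and 0.83 ± 0.06.

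In total 2875 of 13764 tested loci passed the threshold, 1640 higher and 1235 lower in KO, so 57% of the calls were higher. Most changes were small: 930 of the higher and 693 of the lower loci differed by less than 1.5-fold, and 348 higher and 249 lower loci differed at least 2-fold. In CPM, both KO libraries lay on the same side of both WT libraries in all 2875, as did 68.9% of all tested loci, where chance gives 33.3%. CPM scales the libraries otherwise than the normalised counts: Asxl2 went from 127 to 137 in CPM and from 7704 to 8685 in normalised counts. Such an offset between the genotypes can separate unchanged loci, so the 68.9% is no measure of how many loci changed. With upper-quartile scaling 3217 loci passed and 43% of them were higher. Fewer loci passed when either WT library was left out, and more passed when either KO library was left out. In such fits the spread comes from the pair of the other genotype alone. The KO libraries resembled each other less (Spearman correlation 0.9943) than the WT libraries did (0.9959). A call lost without a WT library therefore does not show that it rested on that library. Of 135 named loci other than Asxl1, 61 lost their call without WT replicate 1, 53 without WT replicate 2, 10 without KO replicate 1 and 12 without KO replicate 2.

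**Figure D1:**
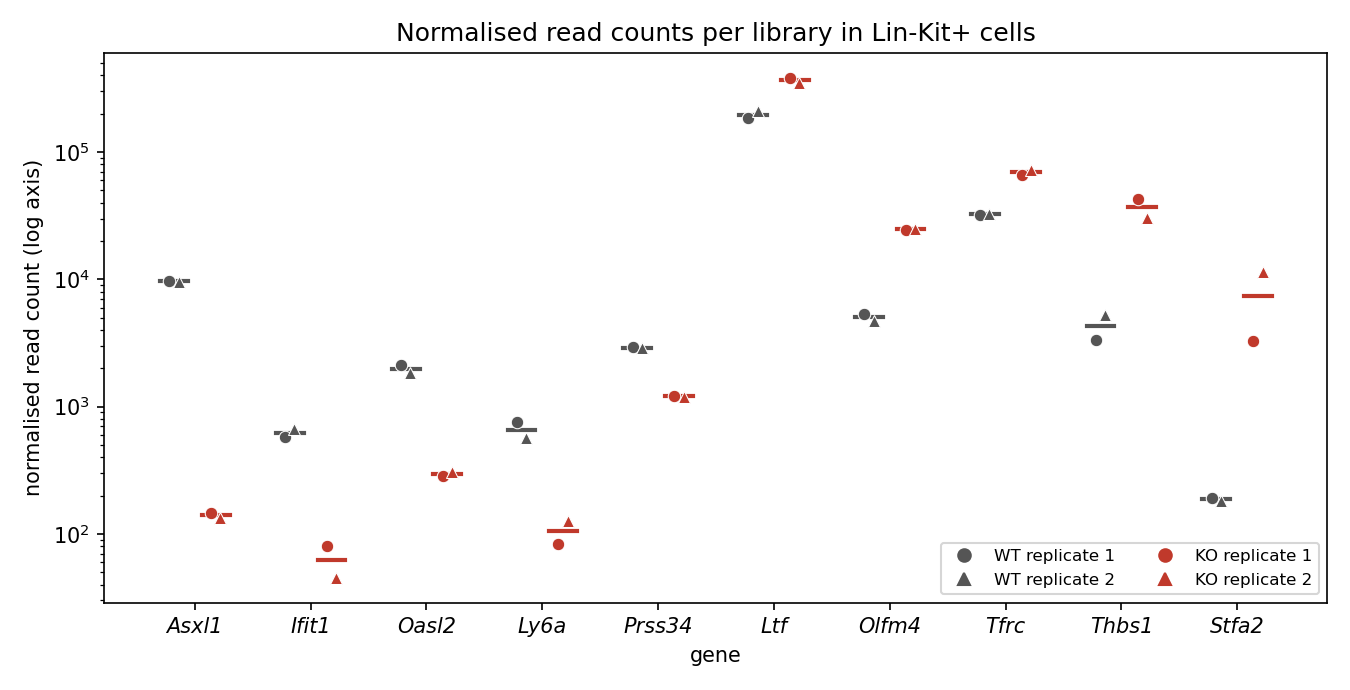
Normalised read counts (log axis) of 10 named genes in each library, with circles for replicate 1, triangles for replicate 2, grey for WT, red for KO and bars at the mean of 2 libraries. Asxl1 lies at 9742 and 9472 in WT and at 146 and 135 in KO, and for each gene both KO libraries lie on the same side of both WT libraries.

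Among the 12 largest rises that the naming rule took, Stfa2 went from 187 ± 5.26 to 7347 ± 5774 (log2 5.03 ± 0.53, adjusted p = 0.00348). That part of the rule left out predicted and clone names and loci under a CPM of 1 in both groups, such as Rpl39l (4.56 ± 0.89). Stfa2l1 rose by 4.59 ± 0.49 and Stfa3 by 4.38 ± 0.55. These copies are near-identical, so how the counting divided reads between them is uncertain, but the summed value over the 8 tested loci of the cluster was 3849 and 3432 in WT and 42186 and 132601 in KO. Slc15a2, a peptide transporter gene in the same region, rose by 5.23 ± 0.74 (adjusted p = 0.0079). Ccnb1ip1, which encodes a ubiquitin ligase with a role in meiosis, had 1 read in both WT libraries together and 1025 in KO, a rate ratio of 616 (95% exact interval 110 to 24400). Smaller rises were found for Trnp1 (4.15 ± 0.62), the collagen gene Col9a2 (3.71 ± 0.61), the adrenergic receptor gene Adra2a (3.38 ± 0.55), Cttnbp2 (3.17 ± 0.42), the merged locus Six6os1+Six6+4930447C04Rik (3.06 ± 0.52) and Tnfaip6 (2.87 ± 0.63). The call of Tnfaip6 was lost without WT replicate 1 and without KO replicate 1, and limma-voom did not call Stfa2, Stfa3 or Trnp1.

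**Figure D2:**
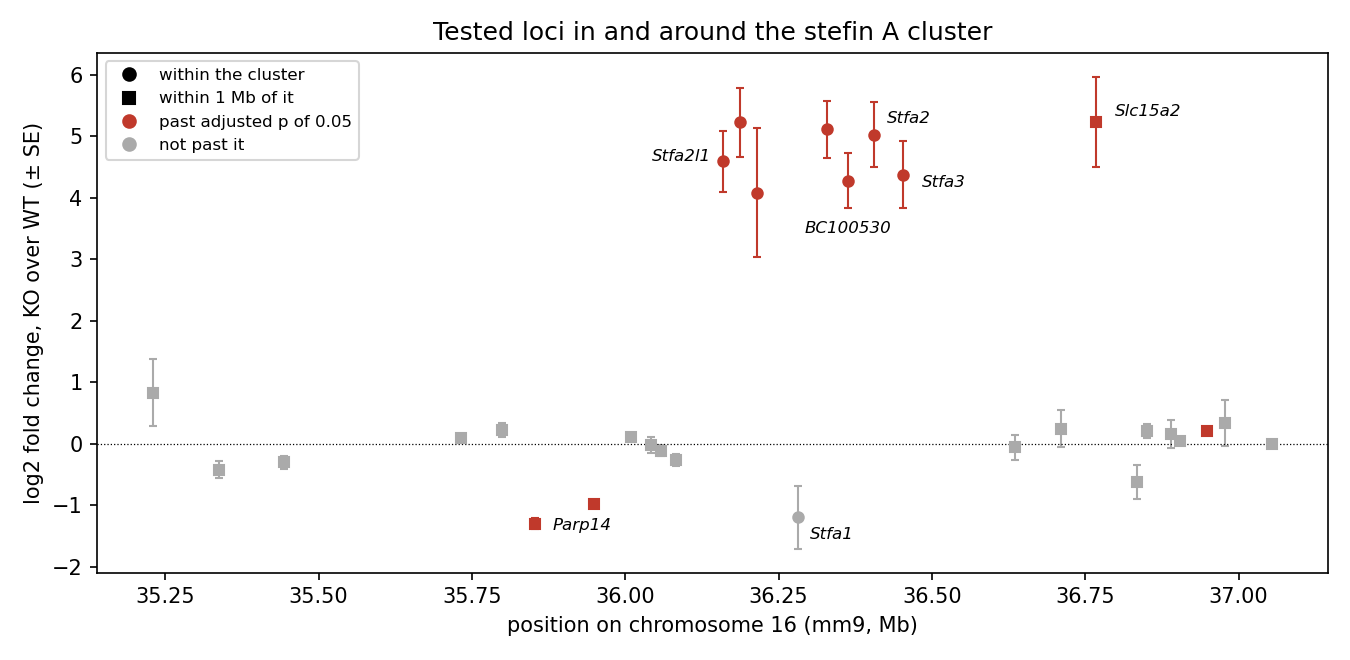
Log2 fold change of KO over WT (± SE) against position in Mb on chromosome 16 (mm9) for the 8 tested loci of the stefin A cluster (circles) and the 21 tested loci within 1 Mb of it (squares), red where past the adjusted p of 0.05. Cluster loci reach 5.23 while Stfa1 lies at -1.20 and did not pass.

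Interferon-stimulated genes formed the group with the strongest shift. Of 37 tested members 33 fell and 0 rose (34 and 0 adjusted over the list alone), with a median of -1.31 (camera adjusted p = 3.12e-22, and adjusted p = 0.597 with an estimated correlation). Ifi44 fell from 785 ± 31.5 to 73.7 ± 19.0 (-3.42 ± 0.22), Ifit1 from 620 ± 59.8 to 62.9 ± 24.7 (-3.33 ± 0.29), Oasl2 from 1974 ± 198 to 296 (-2.73 ± 0.12) and Rtp4 from 1534 ± 59.8 to 238 ± 63.4 (-2.71 ± 0.19). Outside the list, Oas1g (-3.86 ± 0.37) and the interferon-inducible GTPase genes Iigp1 (merged locus Iigp1+IIGP, -3.73 ± 0.25) and Tgtp2 (-2.60 ± 0.28) fell as well. Zbp1, a sensor of nucleic acids, fell by 2.42 on the log2 scale and Kctd17 fell by 2.56, while Rgs8 changed by -4.22 ± 0.34. The list median was -1.21 in the first replicate pair and -1.58 in the second.

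Genes of the mature neutrophil list rose together. The Lin-Kit+ gate should remove mature neutrophils, but these transcripts alone do not tell mature cells from their precursors. Of 23 tested members 22 rose (23 adjusted over the list alone), with a median of 0.97 (camera adjusted p = 6.12e-17, and adjusted p = 0.597 with an estimated correlation). The median was 1.07 in the first pair and 0.86 in the second. Olfm4 rose from 5023 ± 492 to 24718 ± 223 (2.302 ± 0.07), Trem1, a receptor that amplifies inflammatory signals, by 1.76 ± 0.10, the locus AA467197+Mir147 by 1.32 ± 0.12 and Padi4 by 1.13 ± 0.17. Ngp reached 662520 ± 61865 in KO against 349420 ± 47453 in WT. Genes of the earlier primary granules did not shift as a list: 4 of 20 rose and 3 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.522). In that list the transcription factor Cebpe rose by 0.63 ± 0.05 and Fcnb by 0.52 ± 0.13, while Calr (-0.55 ± 0.05) and Plac8 (-0.45 ± 0.07) fell. Its higher count was 1 without WT replicate 1 or 2, and its lower count was 7 without KO replicate 1 and 6 with DESeq2.

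Other myeloid lists moved in both directions. In the monocyte and macrophage list 6 of 27 rose and 6 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.522), with Cd14 up by 1.66 ± 0.24 and Emr1 by 1.003 ± 0.12 and the complement genes C1qa (-0.98 ± 0.26) and C1qb (-0.97 ± 0.20) down. In the dendritic cell and MHC class II list 1 of 20 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.998). Its median was 0.15 and its camera direction was up, while fry gave a downward direction. The interferon-inducible Bst2 fell by 1.499 and Irf4 rose by 0.65 ± 0.11. In the mast cell, basophil and eosinophil list 6 of 24 rose and 5 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.0898). Alox15 (1.78 ± 0.22) and the eosinophil ribonuclease locus Ear2+Ear3 (1.30 ± 0.26) rose, whereas the basophil protease gene Prss34 (-1.26 ± 0.07) and the IgE receptor gene Fcer1a (-1.30 ± 0.34) fell. Leaving out WT replicate 1 or 2 left 1 lower member in the monocyte list, 1 in the dendritic list and 1 in the mast cell, basophil and eosinophil list. Without KO replicate 1, 5 members of the dendritic list and 11 of the mast cell, basophil and eosinophil list were higher, and without KO replicate 2, 9 members of the monocyte list were lower. The dendritic list had 2 lower members with edgeR and RLE or TMM, limma-voom and no filter.

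Stem-cell transcripts were lower in KO. Of 28 HSC-associated genes 14 fell and 0 rose (16 and 0 adjusted over the list alone), with a median of -0.58 (camera adjusted p = 1.33e-05, and adjusted p = 0.597 with an estimated correlation). Ly6a, which encodes the surface antigen Sca-1 and is also induced by interferon, fell from 661 ± 134 to 105 ± 31.4 (-2.66 ± 0.26). Ndn (-1.55 ± 0.39), the interferon-inducible Ifitm1 (-1.41 ± 0.27) and the locus Mecom+AK145113 (-1.39 ± 0.19), which holds a transcription factor of stem cells, fell too. Of 10 tested Hox genes 5 fell (8 adjusted over the list alone), with a median of -0.98 (camera adjusted p = 0.000763, and adjusted p = 0.597 with an estimated correlation), among them Hoxa10 (-1.37 ± 0.28), Hoxa7 (-1.08 ± 0.21), Hoxb4 (-0.98 ± 0.22) and a merged locus with Hoxa3 (-0.98 ± 0.22). The counts for the HSC and Hox lists were 4 and 0 without WT replicate 1, and 4 and 1 without WT replicate 2, and 1 HSC-associated gene was called higher without KO replicate 1 or 2.

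Lymphoid transcripts were lower as well. In the B lineage list 8 of 24 fell and 2 rose (17 and 2 adjusted over the list alone), with a median of -0.46 (camera adjusted p = 0.000282, and adjusted p = 0.597 with an estimated correlation). Dntt, the polymerase that adds nucleotides at antigen receptor joins, fell from 30665 ± 2271 to 17126 ± 5678 (-0.88 ± 0.21), Cd79a by 0.86 and Pou2af1 by 0.79. In the T and NK lineage list 7 of 26 fell and 0 rose, also adjusted over the list alone, with a median of -0.60 (camera adjusted p = 0.000805, and adjusted p = 0.659 with an estimated correlation), including Cd4 (-1.54 ± 0.23), Ccl5 (-1.14 ± 0.28), Thy1 (-1.04 ± 0.23) and Eomes (-0.97 ± 0.26). Stroma and endothelium markers showed 3 of 17 lower and 0 higher, also adjusted over the list alone (camera adjusted p = 0.888; median -0.00, with fry upward): Emcn fell by 1.76, Plvap by 0.98 and Pecam1 by 0.38. The B lineage count was 0 without either WT replicate and 16 or 14 without KO replicate 1 or 2. T and NK and stroma counts were 2 and 0 without either WT replicate, and 1 stroma marker was called higher without KO replicate 1 or 2. No B lineage gene was called higher without either WT replicate. With fry the adjusted p was 0.131 for the B lineage and 0.0765 for the T and NK list.

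Erythroid and megakaryocyte transcripts were higher. Of 32 erythroid genes 16 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 0.44 (camera adjusted p = 3.18e-09, and adjusted p = 0.681 with an estimated correlation). The transferrin receptor gene Tfrc rose from 32409 ± 552 to 69241 ± 4958 (1.09 ± 0.06), Alas2, the erythroid enzyme that starts haem synthesis, by 0.79 ± 0.15, Car1 by 0.75 ± 0.07 and Tspan33 by 0.67 ± 0.15. In the haem synthesis and iron list 7 of 20 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.00351, and adjusted p = 0.682 with an estimated correlation), with Fech and Slc25a38 both up by 0.55 and Abcb10+AK013187 by 0.48. In the megakaryocyte and platelet list 10 of 29 rose and 1 fell (11 and 2 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 0.000171, and adjusted p = 0.659 with an estimated correlation), led by Thbs1 and the merged loci Selp+F5+AK149537 (1.08 ± 0.06), Sept5+Cdcrel-1+Gp1bb (1.03 ± 0.06) and Cnrip1+Plek (0.83 ± 0.07). Higher counts of the erythroid, haem and megakaryocyte lists were 6, 0 and 6 without WT replicate 1, without WT replicate 2 they were 17, 4 and 8, without KO replicate 1 the haem count was 11, and without KO replicate 2 the megakaryocyte count was 19. The lower count of the megakaryocyte list was 0 without either WT replicate, 3 without KO replicate 1 and 2 without KO replicate 2. Upper-quartile scaling gave 4 higher and 1 lower haem and iron genes, and with fry the adjusted p was 0.137 for the erythroid, 0.185 for the haem and 0.124 for the megakaryocyte list.

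Immediate-early genes, which also respond to the handling of cells, were higher in KO. Of 29 members 23 rose and 2 fell (23 and 3 adjusted over the list alone), with a median of 0.83 (camera adjusted p = 7.76e-11, and adjusted p = 0.597 with an estimated correlation). Atf3 rose by 1.70 ± 0.19, Egr3 by 1.62 ± 0.14 and Fosl1+Ccdc85b by 1.59 ± 0.09, whereas the heat shock gene Hspa1b fell by 1.63. In the inflammatory and NF-kB list 13 of 26 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.43 (camera adjusted p = 0.000164, and adjusted p = 0.597 with an estimated correlation), including the neutrophil chemoattractant gene Cxcl2 (437 ± 14.1 to 2005 ± 382, 2.18 ± 0.14), Nlrp3 (1.66 ± 0.13) and the NF-kB inhibitor Tnfaip3 (1.09 ± 0.09). Of 28 p53 targets and apoptosis genes 7 rose and 2 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.118), and the BCL2-family genes Pmaip1 (1.13 ± 0.14) and Bbc3 (1.07 ± 0.17), a merged locus with Gadd45a (0.97 ± 0.06) and Plk2 (0.84 ± 0.14) were among those that rose. In the TGF-beta list 6 of 22 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.054), with Tgfbi (0.86 ± 0.16), Ltbp1 (0.75 ± 0.20) and Id1 (0.72 ± 0.13) beside Thbs1. Id1 lies within 10 Mb of Asxl1. Of 32 cytokine receptor and signalling genes 6 rose and 5 fell (7 and 6 adjusted over the list alone; camera adjusted p = 0.24), with Socs3 (0.87 ± 0.15), Il18r1 (0.64 ± 0.15) and Csf2ra (0.58 ± 0.05) higher and Flt3 lower (-0.61 ± 0.16). Higher counts of the inflammatory, p53, TGF-beta and cytokine lists were 7, 3, 2 and 1 without WT replicate 1. Without WT replicate 2 the TGF-beta and cytokine counts were 1 and 3. The lower count of the cytokine list was 0 without either WT replicate, and that of the p53 list was 1 in both cases and 4 without KO replicate 2. The lower TGF-beta count was 0 without either WT replicate and 2 without KO replicate 1, and the immediate-early and inflammatory lists had 0 lower members without WT replicate 2. With limma-voom and with no filter the higher TGF-beta count was 3.

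Cohesin genes, the group that the series design names, did not shift as a list. Of 22 members 4 rose and 1 fell, also adjusted over the list alone, with a median of 0.06 (camera adjusted p = 0.414). The 4 were Stag3, a meiotic subunit (1681 ± 324 to 2737 ± 171, 0.72 ± 0.14), Wapal, the cohesin release factor (0.30 ± 0.06), the locus Esco1+mKIAA1911 (0.24 ± 0.05) and the loader locus mKIAA0892+Mau2+Kiaa0892 (0.21 ± 0.05). In the kinetochore and spindle checkpoint list 0 of 29 rose and 1 fell, Mis12 by 0.24, and 0 fell adjusted over the list alone (camera adjusted p = 0.414). In the G2 and mitosis list 1 of 24 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.738), namely the locus Spef1+Cdc25b (-0.60 ± 0.10). None of 32 DNA replication genes passed the limma threshold, also adjusted over the list alone (camera adjusted p = 0.835), with 6 at an unadjusted p under 0.05 and 1 called by edgeR with TMM and 2 by DESeq2, and the smallest adjusted p-values were 0.0536 for Uhrf1 (-0.17 ± 0.05) and 0.0651 for Pola1 (-0.16 ± 0.05). Of 28 DNA repair genes 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.428): Brca2 by 0.27 ± 0.05 and Polg+Fanci by 0.18 ± 0.04 up, Atm by 0.38 and Mdc1 by 0.19 down. The cohesin count of higher members was 0 without WT replicate 1 and 2 without WT replicate 2, and no repair gene passed without either WT replicate. Without KO replicate 1, 4 replication genes were higher and 1 was lower, and without KO replicate 2, 4 were lower. The cohesin, kinetochore and mitosis lists had 0 lower members without either WT replicate. Without KO replicate 1 these lists had 2 lower members each and the repair list 4, and without KO replicate 2 the cohesin list had 0 and the kinetochore list 3 lower members, while 2 mitosis genes were higher. Upper-quartile scaling gave 1 higher and 6 lower repair genes, 3 lower replication genes and 2 lower kinetochore genes, DESeq2 gave 4 lower repair and 2 lower kinetochore genes, and limma-voom, no filter, thinned reads and the removal of mitochondrial, ribosomal protein, haemoglobin and histone genes gave 0 lower cohesin and kinetochore genes. The kinetochore count was also 0 with edgeR and RLE, a pseudocount of 0.5 and the joined rows.

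Among chromatin regulators, Polycomb genes fell in part. In that list 5 of 31 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.147). Pcgf2 fell from 306 ± 36.8 to 87.4 ± 10.4 (-1.79 ± 0.20), Cbx2 by 1.06 and Cbx6+Nptxr+Npcd by 0.88, while Tctex-3+Phf1 rose by 0.39 ± 0.09. Of the 10 tested ASXL and BAP1 complex genes Asxl1 fell and Asxl2 rose by 0.17 ± 0.05 (adjusted p = 0.0477), with 3 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.546). The call of Asxl2 was lost whichever library was left out, and under upper-quartile scaling, limma-voom, no filter, thinned reads and the replicate block, and the lower count of this list was 2 without KO replicate 1 or 2 and 3 with upper-quartile scaling. Of 29 genes mutated in myeloid neoplasms 4 rose and 5 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.502), with Tet2 up by 0.61 ± 0.06 and Flt3 (-0.61 ± 0.16), Calr (-0.55 ± 0.05) and Idh2 (-0.38 ± 0.05) down. Without either WT replicate the lower count of the Polycomb list was 3 and its higher count 0, and the myeloid neoplasm list had 1 higher and 1 lower member without replicate 1 and 2 and 2 without replicate 2. Without KO replicate 2, 8 myeloid neoplasm genes were lower.

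Housekeeping groups had small median changes. Of 79 ribosomal protein genes 16 rose and 1 fell (19 and 1 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 2.03e-06, and adjusted p = 0.597 with an estimated correlation), including Rpl39l (2.59 ± 3.66 to 57.9 ± 6.83), Rps29 (0.96 ± 0.09), Rps28 (0.53 ± 0.06) and Rpl37 (0.37 ± 0.06). In the cholesterol synthesis list 6 of 22 fell and 1 rose (8 and 1 adjusted over the list alone), with a median of -0.20 (camera adjusted p = 0.0239, and adjusted p = 0.682 with an estimated correlation). The call of this list was lost with fry (adjusted p = 0.291) and without KO replicate 2 (adjusted p = 0.059). The enzyme genes Sqle (-0.65 ± 0.12) and Cyp51 (-0.57 ± 0.13) fell. Of 24 glycolysis genes 7 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0815), with the glucose transporter genes Slc2a3 (1.16 ± 0.08) and Slc2a1 (0.43 ± 0.10), Gpi1 (0.28 ± 0.05) and Hk1+AK008969 (0.28 ± 0.06). In the MYC and ribosome biogenesis list 1 of 29 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.061), namely Tfrc upward and Mycn (-1.36 ± 0.17), Myc (-0.39 ± 0.05) and Npm1 (-0.22 ± 0.04) downward. Of 77 oxidative phosphorylation genes 3 rose and 4 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.061), with Cox6b2 up by 0.72 ± 0.13, Ndufv3 by 0.48 ± 0.07 and Ndufb6+AK008077+Topors by 0.30 ± 0.05, and Ndufa4 down by 0.28. Leaving out WT replicate 1 or 2, the ribosomal count was 4 or 3, the cholesterol count 2 or 1, the lower MYC count 1 in both cases, and the glycolysis count 1 in both cases, and oxidative phosphorylation had 1 higher and 0 lower members. The lower ribosomal count was 0 without either WT replicate and 2 without KO replicate 2. Without KO replicate 2 the lower counts of the MYC and oxidative phosphorylation lists were 7 and 8 and the glycolysis count was 3, and without KO replicate 1, 5 oxidative phosphorylation genes were higher. Upper-quartile scaling gave 8 ribosomal and 4 glycolysis genes higher and 2 ribosomal, 5 MYC and 13 oxidative phosphorylation genes lower, and DESeq2 gave 28 ribosomal genes higher, 2 lower, and 9 oxidative phosphorylation genes lower.

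Mitochondrial, histone and sex-linked transcripts did not shift as lists. None of 8 mitochondrially encoded loci passed the limma threshold, also adjusted over the list alone (camera adjusted p = 0.564), with 2 at an unadjusted p under 0.05, 0 called by edgeR and 1 by DESeq2, and AK163440 at -0.22 ± 0.07 and AK140265 at 0.10 ± 0.04. Mitochondrial reads made up 2.63% and 2.76% of the WT and 2.58% and 2.49% of the KO libraries. Of 54 replication-dependent histone genes 1 rose and 1 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.522), Hist1h1c by 0.48 ± 0.08 upward and Hist3h2ba by 2.18 downward, and 0 passed without either WT replicate. Without KO replicate 1, 2 histone genes were higher and 1 mitochondrial locus was lower, and without KO replicate 2, 2 histone genes were lower. Upper-quartile scaling called 1 mitochondrial locus lower, and the CPM filter left 0 lower histone genes. None of 5 sex-linked loci passed in limma, edgeR or DESeq2, also adjusted over the list alone and at an unadjusted p under 0.05 (camera adjusted p = 0.82), with Tsix+Xist at -2.03 ± 3.12 and Smcy+Kdm5d at -1.32 ± 3.82, since both genotypes held 1 library of each kind. Without KO replicate 1, which leaves KO with the library high in Y-linked transcripts, Tsix+Xist passed (adjusted p = 0.0479).

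**Figure D3:**
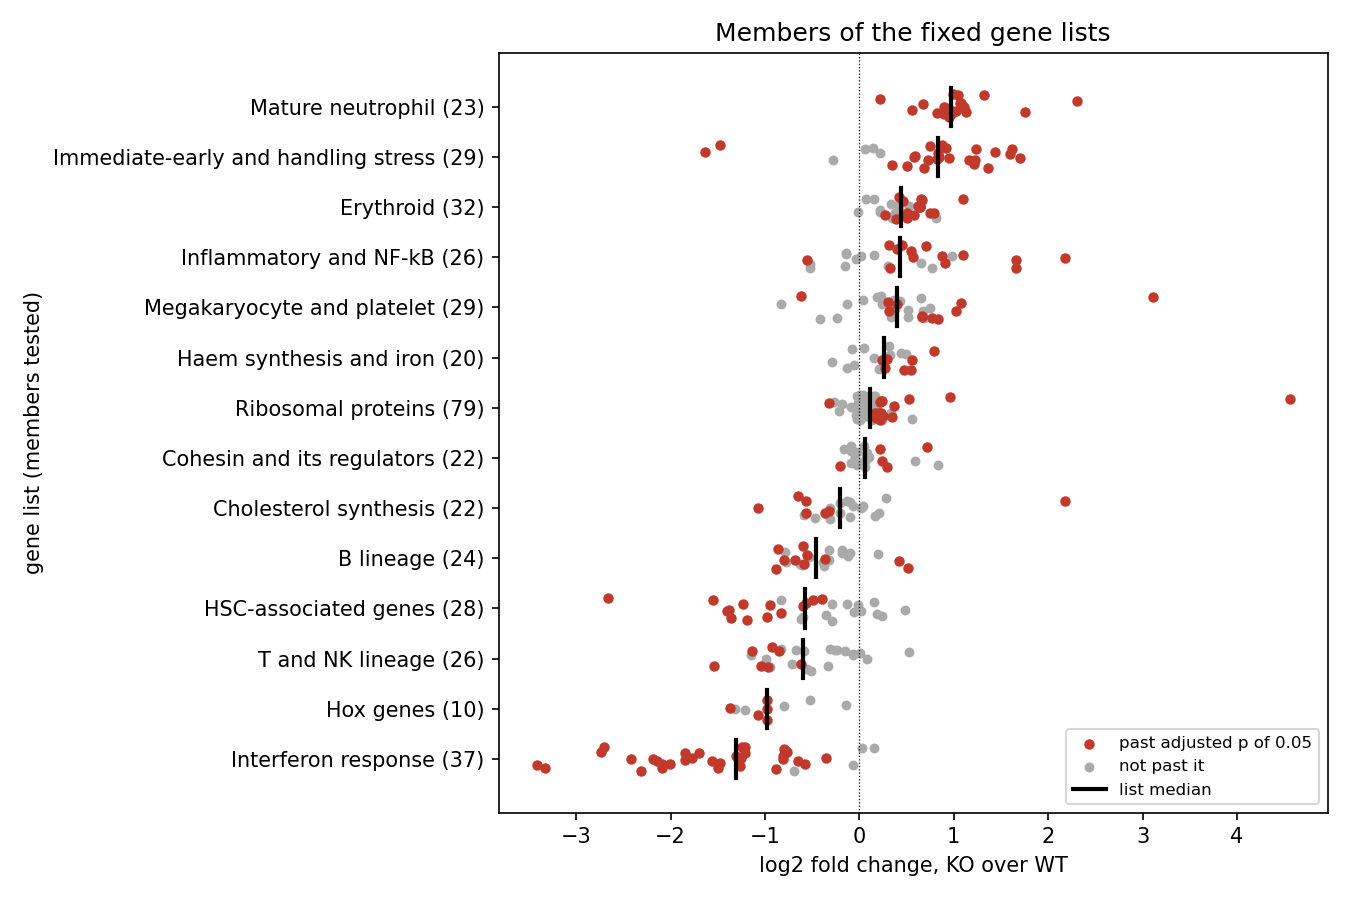
Log2 fold change of KO over WT for each tested member of the 13 lists that camera called and of the cohesin list, red where past the adjusted p of 0.05, with a bar at the list median and the number of members in brackets. The interferon list lies lowest, with a median of -1.31, and the mature neutrophil list highest, with a median of 0.97.

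As a group, genes around the targeted locus were not enriched among the changes. Within 10 Mb of Asxl1 on chromosome 2, 25 of 162 tested loci were called (15.4%; 16 higher and 9 lower), against 20.9% of 13601 other loci. The odds ratio was 0.689 (95% interval 0.43 to 1.06, two-sided Fisher's exact p = 0.0978). Such a count does not speak for single loci, and Id1 (0.72 ± 0.13), called higher, lies in this window. Without KO replicate 1 the ratio was 0.536 and the exact p was 0.0038, so fewer loci near Asxl1 than elsewhere were then called.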

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

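All tests in this part were chosen after the results were seen.

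Rows that join a pair of neighbouring loci lay outside the comparisons, and 17 of 426 tested were called by limma when kept in the fit, 11 higher in KO and 6 lower, the latter by log2 fold changes from -4.64 to -0.45. Among the higher, the KO mean was 80.0 for BC117090 with BC100530 against 3.13 in WT, 25.2 for Igsf5+Pcp4 with Itgb2l against 2.48, and 11.5 for Zmynd17 with Ppp3cb against 0. It was 212 for 4930515G01Rik with Ankrd13a against 42.6, 31.8 for Lysmd1+Tnfaip8l2 with Scnm1 against 9.45, and 47.1 for Snx17 with AK185715+Zfp513 against 15.8. Smaller differences were found for AK169831 with Sorl1 (509 against 317), for Ncl with Snora75 (348 against 204) and for Gnl3+Spcs1+Glt8d1 with Snord69 (170 against 96.1).

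Genes of the mature neutrophil list were higher in KO. The gate selects against mature cells, but the list does not tell mature cells from precursors inside the gate. Deeper KO libraries were argued against by thinning all libraries to equal depth, after which 21 of 23 members were still called higher. More lineage-positive cells of every kind in the sort were argued against only as far as the T and NK list marks mature T and NK cells. Its median was -0.599 (95% order-statistic interval over genes -0.93 to -0.259), and 7 of its 26 members were called lower. That list does not tell mature cells from precursors either, and it cannot speak to a larger carry-over of granulocytes or erythroid cells alone. A single larger share of otherwise unchanged neutrophils cannot be told apart from altered expression, because each member's fold change would also depend on its own level in progenitors. The 95% intervals of 17 of 23 members held the list median. Olfm4, Trem1 and AA467197+Mir147 lay above it and S100a8, Chi3l3 and Csf3r below it, and this count decides neither. An effect of the genotype on the expression of these genes stays open as a hypothesis.

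Interferon-stimulated genes were lower in KO. Fewer dendritic cells were argued against only for the cells that the dendritic list marks as a whole. Without Bst2 its median was 0.167 (interval over genes -0.293 to 0.447), above a cutoff of -0.653 chosen after the results were seen. With Bst2, 4 of its 20 members were called lower and 1 higher. The median cannot speak to a kind of dendritic cell that few members mark. Fewer stem cells were argued against as the whole source only if the HSC list marks stem cells as closely as the interferon list does. Without Ly6a and Ifitm1 its median of -0.527 (interval over genes -0.829 to -0.128) lay above the interferon median of -1.31. Its members Ndn (-1.55) and Mecom+AK145113 (-1.39) fell by more than that median, while 14 of 28 members were not called. A different interferon exposure of the animals cannot be told apart from genotype, because each genotype has 2 libraries and the labels give no litter, housing or infection status, and a segment of another strain with a variant regulator was not tested.

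Stefin A genes on chromosome 16 were higher in KO, and Stfa1 (-1.20 ± 0.52) was the exception in the cluster. Reads shared between near-identical copies were argued against as the source of the rise, since the summed cluster value was at least 10.96 times higher in each KO library than in either WT library, although the division between copies stays uncertain. A copy number change of a wider segment was argued against by the 21 tested loci within 1 Mb outside the cluster, whose median was 0.0415 (interval -0.27 to 0.203), although 1 of them, Slc15a2, rose as much as the cluster, with Cd86 (-0.06 ± 0.21) and Ildr1 (0.25 ± 0.31) between them not called. More neutrophils with the same marker mix in both KO libraries were argued against as the source of the whole rise in the cluster. The 7 called cluster loci rose 2.99 to 3.98 times as much over WT in KO replicate 2 as in KO replicate 1. Ratios of the 23 mature neutrophil members ran from 0.44 to 1.58, with a median of 0.977 (interval over genes 0.819 to 1.03). The test does not cover Slc15a2 (2414 and 1225 in KO replicates 1 and 2). It cannot speak to neutrophils whose stage or mix differed between the KO libraries. A part from neutrophils stays open, since the members' own levels in progenitors can hide a small share, as do an effect of the genotype and, both untested, a copy change limited to the cluster and a different haplotype of the region, which can alter single loci such as Slc15a2.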

How the results depend on the processing

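The added alternatives (edgeR with TMM with and without the block, pseudocounts, TMM rescaling, joined rows, thinning, sex chromosomes left out) were chosen after seeing the data, and the others before. Asxl1 stayed lower and past the threshold in every alternative, from -6.15 to -6.02. Among fits with all 4 libraries at the same threshold, the count of called loci ranged from 2516 without a filter to 3482 with edgeR, TMM and the block, and shared calls had the same sign in each. An adjusted p under 0.10 called 4458 loci (2109 of them lower), and a fold change of at least 2 left 597 (348 higher, 249 lower), both because the threshold itself moved. With one library left out, 869 to 3233 loci were called, 603 to 1714 higher and 266 to 1542 lower, where the lone library is assumed to vary like the pair of the other genotype. The replicate block follows the Xist and Y-linked transcripts but can hold more than sex. Of the 13 loci called by replicate number, 6 lay on X or Y. The block called 3439 loci (1906 higher, 1533 lower), of which 2835 were shared with the fit without it. The block also called 16 lists by camera, with the mast cell, basophil and eosinophil (adjusted p = 0.0387), MYC (0.0446) and TGF-beta (0.0478) lists added to the 13. It gave 14 lower B lineage, 11 lower monocyte, 5 lower primary granule, 4 lower repair, 3 lower ribosomal and megakaryocyte, and 2 lower replication and TGF-beta genes, and 12 higher haem, 11 higher mast cell and 2 higher dendritic genes. Deviations of same-numbered libraries correlated at 0.246 across loci, at 0.575 for loci with a mean of at least 200 and at 0.175 for autosomal loci among these, but no label pairs the libraries. The number of called lists ranged from 11 with fry to 18 at an adjusted p under 0.10, was 0 with camera and an estimated correlation (lowest adjusted p 0.597, with 1 list at an unadjusted p under 0.05), and was 14 to 16 with one library left out. Of the 13 called lists, fry, which tests a list against no change and not against other loci, lost 6 (erythroid, haem, megakaryocyte, B lineage, T and NK, cholesterol). It called the Polycomb (fry adjusted p = 0.0149), myeloid neoplasm (0.00443) and monocyte (0.0441) lists besides. It also called the ASXL and BAP1 list (0.0149), which holds the targeted gene Asxl1 itself. The median log2 fold change of that list was -0.008 and its mean -0.61, so its call is no result about the partners of ASXL1. Leaving out KO replicate 2 lost the cholesterol list. With all 4 libraries, between 0 and 12 of the named loci lost their call in an alternative, most with limma-voom. The odds ratio near Asxl1 was 0.627 with a CPM filter and 0.617 with thinned reads, both then with an exact p under the threshold, and 0.536 to 0.873 with one library left out. Leaving out a library also leaves fewer samples in the fit; the cause of the other differences was not tested.

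Every reversed value concerned a list or locus that passed the threshold neither in the reported fit nor in the alternative that reversed it, and the cause was not tested. For the dendritic and MHC class II list, whose reported mean lies near 0 at 0.0093, the median was 0.1541 with RLE, 0.09765 with upper quartile, 0.1476 without a filter, with fry, with the joined rows and without X and Y, 0.0994 with the CPM filter, 0.1544 with DESeq2, 0.1246 with limma-voom, 0.1493 with edgeR and TMM, 0.1471 with edgeR and the block, and 0.0516 with thinned reads, because the direction comes from the set test and not from the median. The monocyte list stood at -0.2726 with DESeq2 and -0.2863 with edgeR and the block, the stroma list at 0.1732 without a filter and -0.001385 with fry, and the sex-linked list at -0.1916 with upper quartile. With one library left out, medians ranged from -0.1021 to 0.3067 for the dendritic list, -0.008376 to 0.1303 for stroma, -0.08701 to 0.04283 for G2 and mitosis, -0.1387 to -0.03686 for primary granules, -0.03115 to 0.3543 for histones, -0.0322 to 0.1257 for cohesin, -0.03101 to 0.02535 for replication and -5.808 to 4.643 for the sex-linked list, and fold changes from -6.644 to 2.594 for Tsix+Xist, whose lowest value, not reversed, passed without KO replicate 1 (adjusted p = 0.0479), and -6.463 to 3.828 for Smcy+Kdm5d.

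Depth limits loci with few reads: in simulated data, 3 of 23 loci changed 1.5-fold were called below the median level of 1540 and 22 of 27 above it, a split chosen after seeing the data, so a missing call is no evidence of equal expression.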

Other observations

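The values in this part were looked up after the results were seen. Libraries with the same replicate number resembled each other at sex-linked transcripts. The Xist locus had normalised read counts of 103006 in WT replicate 1, 2123 in WT replicate 2, 89290 in KO replicate 1 and 147 in KO replicate 2. The Y-linked locus Ddx3x+Ddx3y stood at 5.2, 7385, 3.8 and 7947 in the same order, and Uty, Eif2s3y and Smcy+Kdm5d followed it. Xist in WT replicate 2 was 2.06% of that in WT replicate 1, and in KO replicate 2 it was 0.164% of that in KO replicate 1. With the replicate number as a term, limma called 13 loci for it, 6 of them on X or Y and 967 at an unadjusted p under 0.05. Outside the sex chromosomes these included Cwc22+AK039942 (-0.84 ± 0.05, replicate 2 over replicate 1), Gm5506+AK180697 (-1.09 ± 0.07), the globin locus Beta-s (0.85 ± 0.06), Pttg1 (-0.78 ± 0.06), which encodes securin, the haem synthesis gene Alad (-0.76 ± 0.07) and Gas2l3 (-0.61 ± 0.06).

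Some transcripts were nearly absent in 1 genotype. AK184713 on chromosome 2 (128996432 to 128997018) had 88 reads in WT and 0 in KO, at least 48.8-fold lower against a floor of 3 reads over the group, which leaves out the counting error of the 88 reads (95% exact lower limit of the rate ratio 38.9). The locus 2610035D17Rik on chromosome 11 had 126 reads in WT and 3 in KO, a rate ratio of 69.9 (95% exact interval 23.4 to 343). In the other direction, Fam71a had 1 read in WT and 85 in KO (ratio 51.1, interval 8.93 to 2040) and Trim72 had 1 and 70 (ratio 42.1, interval 7.31 to 1690). Reads at the Asxl1 locus remained in KO at 1.52% and 1.40% of the WT mean in the 2 libraries.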
